A study of Homo sapiens with 6 samples.

How the data were processed

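The samples were cultures of HT29-tsp53, the human colorectal adenocarcinoma line HT-29 carrying a temperature-sensitive mouse p53 transgene that is inactive at the restrictive temperature and active at 32 °C. Total RNA was measured on 6 Affymetrix Human Gene 1.0 ST arrays, in 3 groups of 2. The control group stayed at the restrictive temperature (p53 off), a second group spent 16 h at 32 °C (p53 on), and the third spent 16 h at 32 °C followed by 6 h of recovery (p53 on then off). Per the labels, the restrictive temperature is 38 °C in some fields and 37 °C in others, and a field of the recovery samples names 32 °C where the rest give a return to the restrictive temperature. The groups follow the sample titles. The labels also give each sample an experiment number, 1 or 2, with each group present in both.

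The deposited values are log2 signals per exon-level probe set, judged from their range of -0.85 to 13.14. The labels give the array and the RNA labelling, while the program that made the values, its background step and its normalization are not given in the sources used here. The columns had medians between 5.24 and 5.31, so no further scaling was applied. Arrays give no read depth, and their number limits the precision.

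Of 257430 probe sets, 224320 carried 1 gene symbol and were used, 10159 carried several and 22951 had no gene listed. A gene's value was the median of its probe sets on each array, over a median of 10 probe sets per gene and 1 probe set for 1060 of 18701 genes. Genes in the lowest 25% by mean signal (under log2 3.62) were left out, leaving 14025 genes. The p53 gene itself was not analysed here. No measure of transcript half-life is among the values, so every result below is a transcript level.

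Groups were compared with limma 3.58.1 in R 4.3.3, with the 3 groups as a single factor over all 6 arrays and a shared, moderated spread. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05 with no minimum fold. With 2 arrays against 2, an exact permutation test of a single gene cannot pass that threshold. Errors beside log2 differences are standard errors from limma with n = 2 arrays per group. On data simulated from these arrays, with 200 changed genes in each of 20 runs, the fit recovered 0.8% of changes of 1 log2 unit, 75.3% of changes of 2 and 95.5% of changes of 3, and 0.0582% of its calls were false. With the experiment number as a replicate block, it recovered 91.7% of changes of 1 log2 unit, and 8.88% of calls were false.

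The experiment number in the labels' descriptions was taken to pair the samples, although no date or batch is given with it. Arrays with the same number also deviated together from their group means, with correlations across genes of 0.496, 0.551 and 0.63 for the pairs of groups. Pearson's r between arrays across genes, which are not independent replicates, lay between 0.911 and 0.975. The unblocked fit had been set as the main one, and values with the replicate block are printed beside it where they change a call or move a count by over 1.5 times.

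Gene lists covered p53 targets of arrest and growth control, of apoptosis and autophagy, of DNA repair and nucleotide supply, and of feedback on p53; G1/S and DNA replication; G2/M and mitosis; replication-dependent histones; heat shock; cold-inducible genes; immediate-early and other short-lived transcripts; the unfolded protein and integrated stress response; cholesterol synthesis; glycolysis and hypoxia; interferon response; ribosomal proteins; ribosome biogenesis; mRNA decay; absorptive, goblet and stem or Wnt genes of the intestine; markers of fibroblasts and leukocytes; reference genes; and genes of the mitochondrial genome. Some genes are on more than 1 list. Lists of at least 5 measured members were tested against the other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over lists within a comparison. The test was repeated with an estimated correlation, and limma's fry tested each list on its own. Fry values are for a shift in 1 direction unless given for members moving either way. Simulated shifts of a list were called in 20 of 20 runs, and 3.61% of 360 tests of unshifted lists fell under 0.05. That simulation drew the noise of each gene independently, so its rates do not cover lists whose members vary together. Estimated correlations were 0.162 for replication genes, 0.28 for mitosis genes and 0.714 for histones. These correlations and all fry tests came from the fit without the block, so a difference between the experiments can enter them.

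The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes, per comparison, the 8 largest rises and 8 largest falls among called genes that moved the same way in both experiments, without small RNAs, pseudogenes and uncharacterised loci. It adds the 2 called members of each list with the largest change, or the member with the smallest p where none was called, given as a value. CDKN1A, MDM2, GDF15, CIRBP and RBM3 are named in every comparison, as are the 8 genes with the smallest and the 8 with the largest share of their rise left after recovery. That share is the difference from control after recovery divided by the difference from control in p53 on, on the log2 scale, for genes called with at least 2-fold change.

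The alternatives were the replicate block, no filter on dim genes, a filter at the lowest 50%, the mean of probe sets, single probe sets, quantile normalization, median centring, a variance trend with and without robust fitting, a fit of only the 2 groups compared, a fold minimum, a linear scale for the share, genes picked in 1 experiment and measured in the other, and leaving out each array in turn. Fits without 1 array carried no block. Where that array belonged to a group compared, the experiments were unbalanced and their difference could enter the result. Where it belonged to the third group, only the estimate of spread changed. Group means under the dim filter value of 3.62 were also raised to it, so that a fold against such a level is given as a lower bound, because the background of the arrays is not given. That step, comparisons of the replication with the mitosis list, of listed p53 targets with other genes, and the block together with an estimated correlation were added after seeing the data. Overlaps of comparisons that share arrays were set against 100 simulations without a recovery effect. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.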

Results

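The arrays measured transcript levels in HT29-tsp53 cells with p53 off, with p53 on for 16 h, and after 6 h of recovery, with n = 2 arrays per group and 14025 genes tested. The series asks how p53-induced expression is reversed and what part mRNA decay has in it. Known p53 targets followed the labels on all 6 arrays. CDKN1A, the p21 inhibitor of cyclin-dependent kinases, stood at log2 signals of 4.83 and 4.99 in control, 8.32 and 7.91 in p53 on, and 4.92 and 4.78 after recovery. MDM2, the ubiquitin ligase that degrades p53, stood at 7.51 and 7.31, then 10.97 and 10.89, then 7.6 and 7.4. GDF15, a stress-induced cytokine, stood at 6.82 and 6.76, then 9.68 and 9.97, then 6.5 and 6.97.

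**Figure D1:**
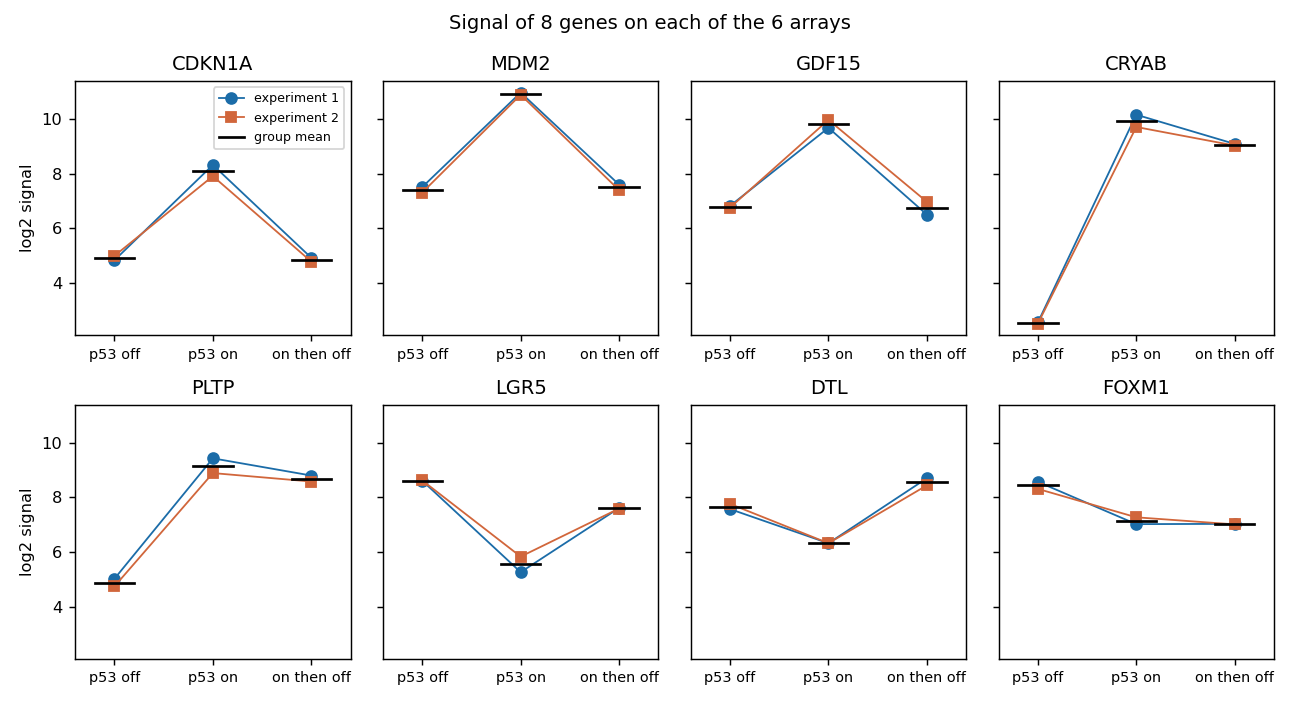
Log2 signal (vertical axis) of 8 genes on each of the 6 arrays, by group, with the experiment number marked. CDKN1A, MDM2 and GDF15 are high on both p53 on arrays and back near control after recovery, while CRYAB is drawn 7.41 log2 units above its dim control level in p53 on and 6.53 above it after recovery.

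The first comparison asks what 16 h of active p53 did to transcript levels. CRYAB, a small heat shock protein and chaperone, had the largest rise, at least 6.32 log2 units (7.41 ± 0.22 as measured, adjusted p = 7.77e-05). TP53INP1, a p53-induced stress protein, rose at least 19.9-fold (5.14 ± 0.46 as measured, adjusted p = 0.00729). These bounds set the control levels, which were under the value used to leave out dim genes, at that value. MDM2 rose 11.5-fold (3.52 ± 0.20, adjusted p = 0.00174), and CDKN1A rose 9.23-fold (3.21 ± 0.22, adjusted p = 0.00334). LGR5, a Wnt-responsive receptor of intestinal stem cells, had the largest fall, by 3.07 ± 0.24 log2 units (adjusted p = 0.00444).

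Among the other large rises were genes of several functions. GADD45A, a growth arrest gene, rose 11.1-fold, the death receptor gene FAS 9.85-fold and GDF15 8.21-fold. The lipid transporter gene ABCA12 rose at least 11.1-fold from a control level under the dim filter, PLTP, which encodes the phospholipid transfer protein, 19.4-fold, and the cytidine deaminase gene APOBEC3C 13.4-fold on a single probe set. Adjusted p for these genes lay between 0.00174 and 0.00454, and standard errors between 0.20 and 0.32. The other large falls, in log2 units, were in the guanine deaminase gene GDA (-2.21), FAM111B (-2.07), ST20 (-2.07 on a single probe set), the tight junction gene CLDN2 (-2.03), the transcription factor gene MYBL1 (-1.87), GINS2, a subunit of the replicative helicase (-1.87), and the adrenergic receptor gene ADRA2A (-1.85). ST20 and MYBL1 fell to levels under the dim filter, and with those levels raised to it the differences were -1.94 and -1.27. Adjusted p for these falls lay between 0.02 and 0.0466, and standard errors between 0.22 and 0.34.

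In all, 126 genes rose and 82 fell, each at least 2-fold and with the same sign in both experiments. With the experiment number as a replicate block, the counts were 726 higher and 881 lower. Leaving out 1 array lowered the counts to 7 higher and 0 lower without control array 1, 3 and 0 without control array 2, 26 and 5 without p53 on array 1, 39 and 1 without p53 on array 2, and 46 and 4 without either recovery array, which carry only the estimate of spread. In limma, 2164 genes had an unadjusted p under 0.05, or 3742 with the block, where chance gives 701. CRYAB, GADD45A and APOBEC3C stayed called in all 6 of these fits, while MDM2, TP53INP1 and PLTP stayed called in 5 and CDKN1A, GDF15, FAS, ABCA12, RRM2B, DDB2 and LGR5 in 4. GDA, GINS2 and DDIT4 stayed called in 2, FAM111B and ST20 in 1, and CLDN2, MYBL1, ADRA2A, MCM10, FOXM1, MUC2, SPDEF, FKBP4, DUSP6 and HIST1H2BM in 0, so these calls rest on having all 6 arrays.

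The lists of p53 targets had positive medians in p53 on, and only arrest and growth targets passed with an estimated correlation. Of 18 measured targets of arrest and growth control, 8 rose over all genes tested and 15 when adjusted over the list alone, with a median of 1.63 (camera, adjusted p = 8.64e-19, and adjusted p = 0.0475 with an estimated correlation, or 0.0931 with the block as well). GADD45A and CDKN1A had the largest rises among them, and 14 rose with the block. Of 17 apoptosis and autophagy targets, 8 rose and 11 when adjusted over the list alone, led by TP53INP1 and FAS (median 1.35, adjusted p = 2.26e-13, but adjusted p = 0.185 with an estimated correlation). Of 13 DNA repair and nucleotide supply targets, 6 rose, and 8 rose and 2 fell with the block and when adjusted over the list alone (median 1.56, adjusted p = 2.64e-07, but adjusted p = 0.257 with an estimated correlation). The ribonucleotide reductase subunit gene RRM2B rose by 2.85 ± 0.23 (adjusted p = 0.00444) and the damage recognition gene DDB2 by 2.55 ± 0.19 (adjusted p = 0.00398). Of 13 feedback genes, 4 rose, 9 with the block and 6 when adjusted over the list alone, led by TP53INP1 and MDM2 (median 1.22, adjusted p = 1.13e-09, but adjusted p = 0.257 with an estimated correlation). That median was 0.73 without p53 on array 1. In fry, which tests a list on its own, adjusted p was 0.00218, 0.0103, 0.0218 and 0.026 for these lists in turn. Of the 126 genes that rose, 22 were on a p53 list.

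Several replication genes fell in p53 on, and the cell cycle lists had medians below 0. Of 34 measured G1/S and replication genes, 7 fell, 19 with the block and 13 when adjusted over the list alone (median -0.76, adjusted p = 2.29e-13, but adjusted p = 0.257 with an estimated correlation). GINS2 and MCM10, a replication initiation factor that fell by 1.67 ± 0.22 (adjusted p = 0.0245), led them. Of 39 G2/M and mitosis genes, FOXM1, a transcription factor of mitotic genes, was the only member called without the block, at -1.30 ± 0.21 (adjusted p = 0.0436). With the block 19 mitosis genes fell, and 15 fell when adjusted over the list alone (median -0.64, adjusted p = 2.26e-13, but adjusted p = 0.289 with an estimated correlation). All 18 measured replication-dependent histones lay below control with a median of -0.98 (adjusted p = 9.21e-06, but adjusted p = 0.628 with an estimated correlation, or 0.0931 with the block as well). Only HIST1H2BM was called (fell by 1.41 ± 0.19, adjusted p = 0.0256), as when adjusted over the list alone, and 12 histones fell with the block. Many of these genes are near-identical copies within a histone family, and their probe sets may cross-hybridise. The list spans several families, linker histones among them. The list's median was -0.39 without control array 1 and -0.35 without p53 on array 2, but -0.96 and -0.973 within the experiments. In fry, adjusted p was 0.0385 for replication genes, 0.0911 for mitosis genes and 0.465 for histones.

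Among 19 heat shock genes, FKBP4, a cochaperone of HSP90, was the only call without the block (fell by 1.26 ± 0.21, adjusted p = 0.0471). With the block 1 rose and 8 fell, and 1 rose and 7 fell when adjusted over the list alone. The list's median was -0.54 (adjusted p = 3.13e-05, but adjusted p = 0.513 with an estimated correlation and 0.191 in fry), or -0.35 without p53 on array 2. The cold-inducible RNA-binding genes were not called. CIRBP differed by 1.10 ± 0.23 (adjusted p = 0.0813) and RBM3 by 1.06 ± 0.42 (adjusted p = 0.299), and the block called both (adjusted p = 0.00916 and 0.00694), as did the test adjusted over the list alone, with 2 of 2 higher.

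Single members of other lists moved while the lists did not pass as a shift in 1 direction. In fry for members moving either way, adjusted p was 0.000292 for stem and Wnt, 0.000691 for goblet and 0.0016 for short-lived genes. It was 0.0284 for cholesterol genes and 0.0295 each for glycolysis and hypoxia genes and for interferon genes. Single members can carry that test. DDIT4, an inhibitor of mTORC1 counted among the 27 glycolysis and hypoxia genes, rose by 2.36 ± 0.37 (adjusted p = 0.0422). Among 12 goblet genes, the mucin gene MUC2 rose by 1.40 ± 0.21 (adjusted p = 0.0362) and SPDEF, a transcription factor of goblet cells, fell by 1.36 ± 0.23 (adjusted p = 0.0491). DUSP6, a phosphatase of ERK, fell by 1.67 ± 0.24 among 40 immediate-early and short-lived transcripts (adjusted p = 0.0337). LGR5 was the only called member of 15 stem and Wnt genes, whose median of 0.06 and mean of -0.23 differ in sign. Adjusted over the list alone, 1 glycolysis and hypoxia gene rose and 1 fell, 1 goblet gene rose and 1 fell, 1 short-lived transcript fell, 1 stem or Wnt gene fell, and 2 interferon genes rose and 1 fell. With the block, 4 glycolysis and hypoxia genes rose and 2 fell, 1 goblet gene rose and 2 fell, 2 stem or Wnt genes fell, 2 short-lived transcripts rose and 2 fell, and 2 interferon genes rose and 1 fell.

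Without the block, no member was called over all genes among 48 mRNA decay genes (median -0.04, adjusted p = 0.847), 20 interferon genes (0.991), 24 unfolded protein and integrated stress genes (0.181), 19 cholesterol genes (0.81), 16 absorptive genes (0.876), 34 ribosome biogenesis genes (0.637), 13 reference genes (0.637), or 6 fibroblast and 6 leukocyte markers (0.735 and 0.427). With it, 1 mRNA decay gene and 2 cholesterol genes rose, and 2 unfolded protein or integrated stress genes, 2 absorptive genes and 1 ribosome biogenesis gene fell. The 36 ribosomal protein genes had a median of 0.19 (adjusted p = 0.117), with adjusted p = 0.0134 under the replicate block but 0.726 with the block and an estimated correlation. Their median was 0.54 without control array 1 and 0.61 without p53 on array 2, but 0.202 and 0.121 within the experiments. Without 1 array of a group compared and without the block the experiments are unbalanced. In such fits medians were 0.36 for glycolysis and hypoxia genes (without control array 1) and -0.36 for ribosome biogenesis genes (without p53 on array 1). The stem and Wnt median was -0.19 without p53 on array 2. No gene of the mitochondrial genome was measured. In lists where no member was called, the member with the smallest p is given as a value. Of these members, the block called FDFT1 at 0.91 (adjusted p = 0.0904, block 0.0161), MANF at -0.85 (0.2, block 0.0217), USP18 at -1.22 (0.0628, block 0.00681), ZFP36L2 at 0.80 (0.239, block 0.0223) and UTP20 at -1.11 (0.0872, block 0.0113). CEACAM7, THY1, TBP, CD68 and RPL32 lay between -0.68 (TBP) and 0.89 (RPL32), with adjusted p of 0.248 to 0.714.

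**Figure D2:**
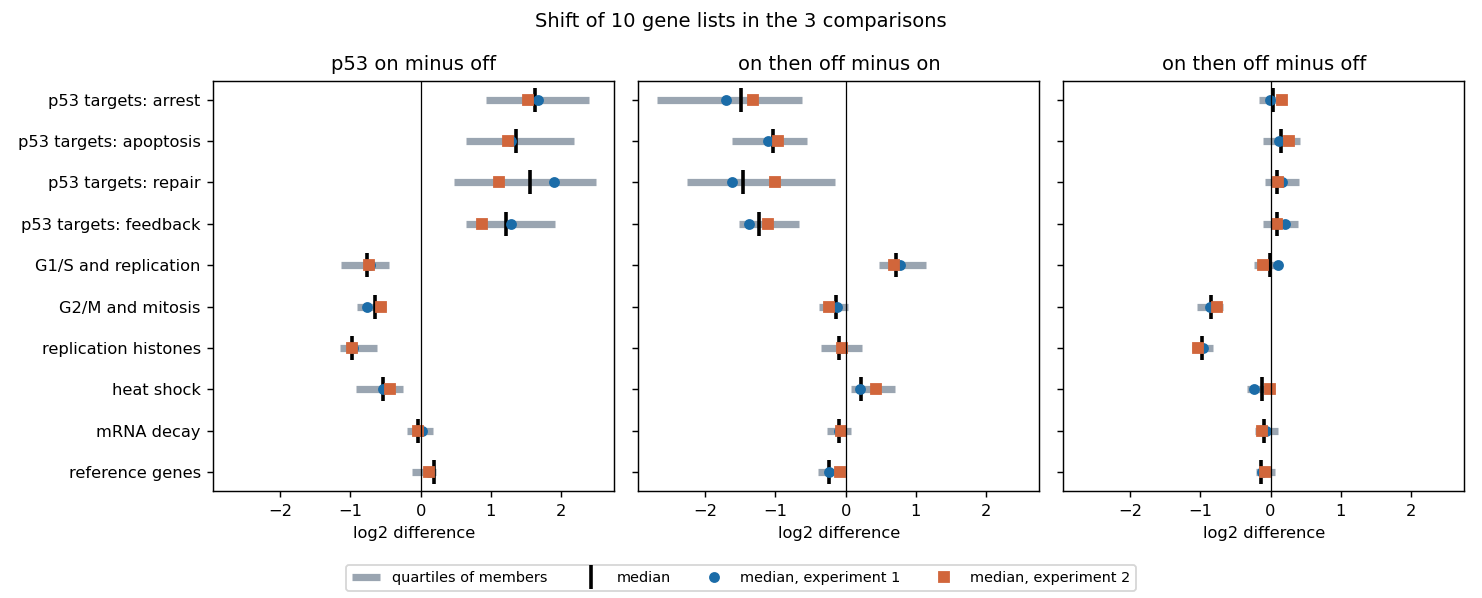
Log2 difference (horizontal axis) of the members of 10 gene lists in the 3 comparisons, with bars for the quartiles of members, a tick for the median and points for the median in each experiment. The p53 target lists lie above 0 in p53 on and near 0 after recovery, while G2/M genes keep a median of -0.85 and histones of -0.98 after recovery.

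The second comparison asks what 6 h of recovery changed relative to p53 on. Listed p53 targets were among the largest falls. TP53INP1 fell at least 19.9-fold, to a level under the dim filter (-4.71 ± 0.46 as measured, adjusted p = 0.0179), MDM2 10.8-fold (-3.44 ± 0.20, adjusted p = 0.00679) and CDKN1A 9.61-fold (-3.27 ± 0.22, adjusted p = 0.00774). FAM111B rose 5.25-fold (2.39 ± 0.27, adjusted p = 0.0269), DTL, which marks the licensing factor CDT1 for destruction, 4.76-fold (2.25 ± 0.20, adjusted p = 0.016), and LGR5 4.16-fold (2.06 ± 0.24, adjusted p = 0.0272).

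Further falls included ANKRA2 (at least 5.79-fold, to a level under the dim filter), GADD45A (8.68-fold), GDF15 (8.55-fold), the cyclooxygenase gene PTGS2 (7.88-fold) and TNFSF10, which encodes the death ligand TRAIL (7.75-fold), with adjusted p between 0.00679 and 0.0364 and standard errors between 0.20 and 0.47. Further rises included the mismatch repair gene MSH6 at 1.85 log2 units, ADRA2A at 1.90, the replication initiation genes MCM10 and CDC6 at 1.79 each, and the serotonin receptor gene HTR1D at 1.74 (adjusted p between 0.0272 and 0.0367, standard errors between 0.21 and 0.23). In all, 20 genes rose and 40 fell, with 1720 at an unadjusted p under 0.05 in limma, and the replicate block gave 539 and 476, with 3114. Without 1 array, 0 rose in each of the 6 fits, 4 fell without p53 on array 1, 2 fell without p53 on array 2, and 0 fell without any of the other arrays. MDM2 and CDKN1A stayed called in 2 of these fits, GADD45A and PTGS2 in 1, and the other genes named as called in this comparison in 0. A fit of only the groups compared gave 0 and 0.

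The p53 lists had negative medians, and only arrest and growth targets passed with an estimated correlation. Of the arrest and growth targets, 6 of 18 fell, 13 with the block and 13 when adjusted over the list alone (median -1.49, adjusted p = 1.14e-21, and adjusted p = 0.0384 with an estimated correlation, or 0.136 with the block as well), led by CDKN1A and GADD45A. Of the apoptosis targets, 4 of 17 fell, 11 with the block and 10 when adjusted over the list alone (median -1.03, adjusted p = 5.69e-15, but adjusted p = 0.155 with an estimated correlation), and FAS fell by 2.86 ± 0.27 (adjusted p = 0.016). Of the repair targets, 4 of 13 fell, and 8 fell and 2 rose with the block and when adjusted over the list alone (median -1.45, adjusted p = 1.17e-07, but adjusted p = 0.208 with an estimated correlation). RRM2B fell by 2.44 ± 0.23 (adjusted p = 0.016), and the fructose bisphosphatase gene TIGAR, listed under its older symbol C12orf5, fell by 2.28 ± 0.31 (adjusted p = 0.0438). Of the feedback genes, 4 of 13 fell, 9 with the block and 7 when adjusted over the list alone (adjusted p = 2.68e-11, but adjusted p = 0.208 with an estimated correlation). Adjusted p by fry lay between 0.00227 and 0.0307 for these lists.

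Recovery moved replication and mitosis genes differently. Of 34 G1/S and replication genes, 4 rose, 16 with the block and 13 when adjusted over the list alone (median 0.72, adjusted p = 2.81e-12, but adjusted p = 0.208 with an estimated correlation), among them DTL and MCM10. In limma, 0 of the 39 mitosis genes were called without the block, 2 fell with it and 0 passed when adjusted over the list alone, and their median was -0.14 (adjusted p = 0.0377, but adjusted p = 0.966 with an estimated correlation). That shift was not past the threshold without p53 on array 1 (-0.07, adjusted p = 0.383) or recovery array 2 (-0.05, adjusted p = 0.472), and it was -0.21 without recovery array 1 and -0.27 without p53 on array 2. The difference between the lists, a comparison added after seeing the data, was 0.86 log2 units (adjusted p = 2.96e-10, and adjusted p = 0.0393 with an estimated correlation, or 0.0693 with the block as well), with 0.899 and 0.929 in the experiments. In fry, adjusted p was 0.038 for replication genes and 0.803 for mitosis genes.

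Heat shock genes had a median of 0.21 (adjusted p = 0.00535, but adjusted p = 0.966 with an estimated correlation and 0.544 in fry), with 0 called without the block, 5 higher and 1 lower with it and, adjusted over the list alone, 3 higher and 1 lower. Without p53 on array 2 their adjusted p was 0.0752, and their median was 0.47 without p53 on array 1 or recovery array 2. Histones had a median of -0.09 (adjusted p = 0.711, or 0.962 in fry, 0 called without the block and 1 lower with it), with -0.046 and -0.045 within the experiments. Without recovery array 1 and p53 on array 2, which unbalances the experiments, the histone median was -0.66 and -0.71. Without the block, LGR5 was the only called member among the remaining lists, for which adjusted p lay between 0.181 and 0.966. Of these lists, short-lived (adjusted p = 2.34e-05), stem or Wnt (0.00186) and goblet genes (0.0119) passed in fry for members moving either way. Without p53 on array 2, which unbalances the experiments, medians were -0.293 for cholesterol, -0.362 for reference and -0.171 for mRNA decay genes. They were -0.385 for ribosomal protein and 0.186 for stem or Wnt genes in that fit. Without p53 on array 1 the ribosome biogenesis median was 0.419. Adjusted over the list alone, 1 absorptive, 1 goblet, 2 short-lived, 1 interferon and 1 stem or Wnt gene rose, and 1 cholesterol, 1 cold-inducible, 1 glycolysis and 1 goblet gene fell. With the block, 1 absorptive, 1 stress, 2 glycolysis, 1 goblet, 2 short-lived, 1 interferon, 1 ribosome biogenesis and 2 stem or Wnt genes rose, and 2 cholesterol, 1 cold-inducible, 1 stress, 2 glycolysis, 2 goblet, 3 short-lived and 1 mRNA decay gene fell. Of the members with the smallest p in lists where none was called, the block called DDIT4 at -2.17 (adjusted p = 0.079, block 0.00407), USP18 at 1.43 (0.0712, block 0.00608), DUSP6 at 1.33 (0.0868, block 0.00578), FABP1 at 1.29 (0.0963, block 0.0136, or 1.04 with its dim level in p53 on raised to the filter value), SPDEF at 1.21 (0.0942, block 0.00731), FKBP4 at 1.14 (0.0881, block 0.0088) and UTP20 at 1.13 (0.122, block 0.0151). The block also called FDFT1 at -1.07 (0.0942, block 0.0127), CIRBP at -0.92 (0.167, block 0.0258), EDEM1 at -0.76 (0.239, block 0.0428) and DLGAP5 at -0.75 (0.235, block 0.0352). CSF1R, GUSB, RBM3, THY1, RPL22, HIST1H2BM and PAN2 lay between -0.59 (CSF1R) and 0.64 (PAN2), with adjusted p of 0.246 to 0.838.

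The reversal was measured gene by gene. Of the 126 genes that had risen in p53 on, 38 fell in recovery, and they made up 38 of the 40 falls. Of the 82 that had fallen, 19 rose, and they made up 19 of the 20 rises. Independent lists would share 0.359 and 0.117 genes, and 100 simulations without a recovery effect gave 0 and 0, a value that the unblocked fit fixes, since it made 0 calls in simulated data with no change. With the block the overlaps were 357 and 378 (24.6 and 33.9 for independent lists, 0.21 and 0.25 simulated). Both comparisons use the same p53 on arrays, so part of the excess may come from them. With the rise taken from experiment 1 and the reversal from experiment 2, 141 genes rose and then fell at least 2-fold, against 8.47 for independent lists, and 155 against 9.19 the other way round. For falls and then rises the counts were 103 against 8.94 and 137 against 12. Without p53 on array 1 or 2 the first overlap was 4 or 2, without any other array it was 0, and the second overlap was 0 in all 6 such fits.

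The median gene that had risen kept 24.8% of its log2 rise (quartiles 6.81% and 47.5%), 22.7% in experiment 1 and 27.4% in experiment 2. Of the 208 genes called in p53 on, 28 had a group mean under the dim filter value, and with such means raised to it the median was 19.7%. The median gene that had fallen kept 19.7% of its fall (quartiles 0.0261% and 43.5%), with 29.7% for the larger set called with the block. PHLDA3, an inhibitor of AKT signalling, PTGS2, the cholesterol exporter gene ABCA1, DTX4, LIMK2 and the translesion polymerase gene POLH had the smallest shares, from -45.9% to -11% of their rise, without differing from control after recovery by the test (adjusted p of 0.876 to 0.999). ANKRA2 (-17.5%) and BLNK (-13.8%) also had small shares (adjusted p = 0.999 against control), but their levels after recovery were under the dim filter, and with levels raised to it the shares were 0% and -1.86%. SERPINB7 (123%), the troponin gene TNNC1 (107%), PLTP (89%), CRYAB (88.2%, or 86.1% with its control level raised to the dim filter), TSNARE1 (84.3%), LAPTM5 (81.2%), the secretoglobin gene SCGB1A1 (80.1%) and the epithelial transcription factor gene ELF5 (77.9%) had the largest shares. Of these, PLTP, CRYAB and SCGB1A1 were called against control after recovery without the block, and SERPINB7, TNNC1, TSNARE1 and LAPTM5 with the block alone. Of the genes named for their shares, PHLDA3, ABCA1, ANKRA2, DTX4, LIMK2, SERPINB7, TNNC1, TSNARE1 and ELF5 stayed called in p53 on in 0 of the 6 fits without 1 array, PTGS2 and BLNK in 1, POLH in 2, and LAPTM5 and SCGB1A1 in 4. The share left of the rise was 46.9% without control array 1, 69.3% without control array 2, 15.7% and 17.9% without p53 on arrays 1 and 2, and 17.8% and 19% without recovery arrays 1 and 2, each over the genes called in that fit. For the fall it was 44.9% without recovery array 1, 37.1% without recovery array 2 and 30.3% without p53 on array 2, and without either control array no gene had fallen.

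**Figure D3:**
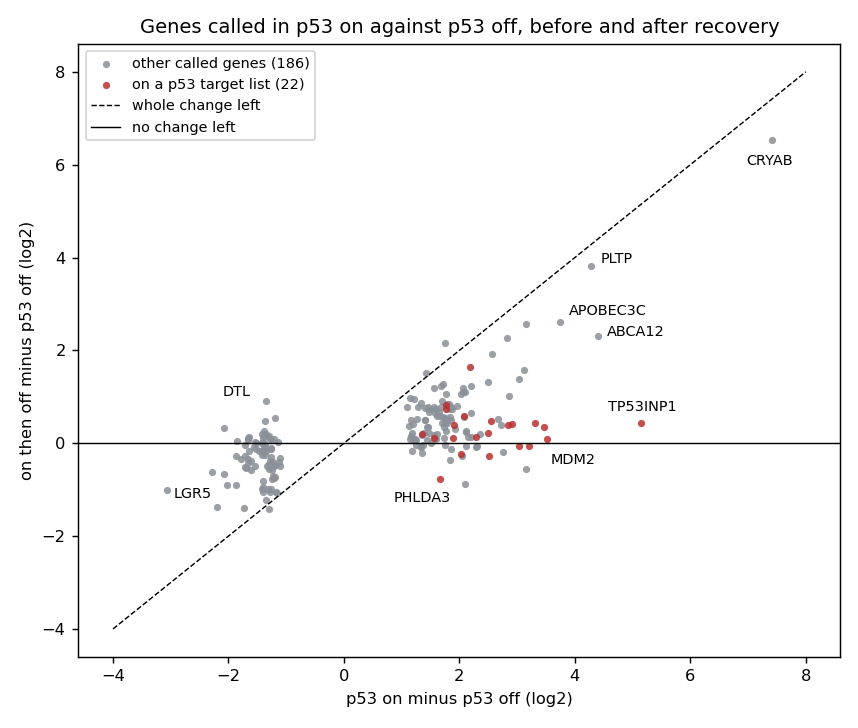
Log2 difference from control in p53 on (horizontal axis) and after recovery (vertical axis) for the 208 genes called in p53 on against control, with the 22 that are on a p53 list marked. Most points lie near 0 on the vertical axis, and CRYAB and PLTP stay high at 6.53 and 3.81.

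The third comparison asks what still differed from control after recovery. CRYAB remained at least 43.5-fold above control, whose level was under the dim filter (6.53 ± 0.22 as measured, adjusted p = 0.000186), and PLTP 14.0-fold (3.81 ± 0.26, adjusted p = 0.0101). APOBEC3C was 6.07-fold above control on its single probe set (2.60 ± 0.20, adjusted p = 0.0154), and SCGB1A1, a secreted airway protein, was 4.78-fold above (2.26 ± 0.20, adjusted p = 0.0297). CDKN1A (-0.06 ± 0.22), MDM2 (0.09 ± 0.20) and GDF15 (-0.06 ± 0.24) had an adjusted p of 0.999 each.

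These 4 genes were the only ones called higher, and 0 were called lower, with 746 at an unadjusted p under 0.05 in limma against 701 by chance. With the replicate block, 29 were higher and 55 lower, with 1821 at an unadjusted p under 0.05. The count was 1 without either control array or either recovery array and 3 without either p53 on array. CRYAB stayed called in all 6 of these fits, APOBEC3C and PLTP in 2 and SCGB1A1 in 0.

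All 39 G2/M and mitosis genes lay below control after recovery, with a median of -0.85 (adjusted p = 2.06e-35, but adjusted p = 0.486 with an estimated correlation and 0.266 in fry). No member was called over all genes, 24 fell when adjusted over the list alone, and 10 fell with the block. FOXM1 differed by -1.42 ± 0.21 (adjusted p = 0.263, block 0.0267). All 18 replication-dependent histones also lay below control, with a median of -0.98 (adjusted p = 4.26e-12, but adjusted p = 0.837 with an estimated correlation, 0.0842 with the block as well, and 0.861 in fry). Of these, 0 were called over all genes, 1 fell when adjusted over the list alone and 8 fell with the block, and HIST1H2BM differed by -1.04 ± 0.19 (adjusted p = 0.483, block 0.0413). The histone median was -0.41 and -1.48 without control arrays 1 and 2, and -1.53 and -0.50 without recovery arrays 1 and 2. These fits carried no block and left the experiments unbalanced, and within the experiments the histone medians were -0.959 and -1.032. The G1/S and replication genes had a median of -0.01 (adjusted p = 0.586). Replication and mitosis genes differed by 0.85 log2 units (adjusted p = 2.63e-12, and adjusted p = 0.0393 with an estimated correlation, or 0.0693 with the block as well), in a comparison added after seeing the data. In p53 on against control they differed by -0.12 (adjusted p = 0.793).

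The p53 lists had medians between 0.04 and 0.14 (adjusted p between 0.19 and 0.715) with no member called over all genes. TP53I3, a p53-induced quinone oxidoreductase gene, was the only p53 target called with the block and past the test adjusted over the list alone (1.64 ± 0.22, adjusted p = 0.246 over all genes, block 0.0117). The unfolded protein and integrated stress genes had a median of -0.19 (adjusted p = 0.0397, but adjusted p = 0.837 with an estimated correlation and 0.861 in fry), with adjusted p = 0.494 without recovery array 1 and 0.236 without control array 2. Heat shock genes (median -0.12, adjusted p = 0.0664) and ribosomal protein genes (median 0.18, adjusted p = 0.117) passed with the block (adjusted p = 0.0215 and 0.0124), though not with an estimated correlation as well (adjusted p = 0.818 for each). No other list passed with all arrays, and no list passed in fry for members moving either way (adjusted p of 0.0679 or more). In unblocked fits without 1 array, which leave the experiments unbalanced, the heat shock median was -0.358 without control array 2. The ribosomal protein median was 0.514 and 0.457 without control array 1 and recovery array 2. The interferon median was 0.24 without control array 1. Among absorptive genes, 1 rose and 1 fell with the block and when adjusted over the list alone, and with the block 1 goblet gene fell. FABP1, a fatty acid binding protein of enterocytes, differed by 1.57, or 1.04 with its dim control level raised to the filter value (adjusted p = 0.316, block 0.0331), CIRBP by 0.18 (adjusted p = 0.999) and RBM3 by 0.68 (adjusted p = 0.997). The members with the smallest p of the remaining lists lay between -1.02 (LGR5) and 0.95 (IFI35), with adjusted p of 0.652 to 0.999.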

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

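The comparison of listed with other genes, that of mitosis with replication genes, and the tests by single experiment, histones and temperature were chosen only after the results were seen. Signal in data left out of the comparisons was tested with limma in the same way. Among 24832 probe sets with no gene or several genes listed, 1 was higher in p53 on than in control, by 4.98 log2 units. Among the 4676 genes left out as dim, 3 were higher in p53 on, and they were chosen after their values were seen: PSTPIP2 (at least 1.84, 3.45 ± 0.36 as measured, adjusted p = 0.0214), the TGF-beta family ligand gene NODAL (at least 1.36, 2.02 ± 0.26 as measured, adjusted p = 0.0445) and LRRC39 (at least 0.15, 2.19 ± 0.25 as measured, adjusted p = 0.0214). The bounds set their control levels, all under the dim filter value, at that value.

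Listed p53 targets that rose kept less of their rise after recovery than the other genes that rose, with a median of 9.47% for 22 genes against 31.7% for 104 (difference -22.2 percentage points, permutation p = 0.02 from 100000 two-sided permutations over genes, which are not independent replicates). Leaving out 1 array moved the difference to -71.7 and -65.9 without control arrays 1 and 2 and -37.4 without p53 on array 1, over the genes called in each fit, and over the other arrays it lay between -23.7 and -14.9. The listed genes had also risen more, by a median of 2.39 against 1.72, but set against the genes nearest in rise they still differed by -39.1 points (95% bootstrap interval -44.4 to -6.81). Another gene could be matched to several listed genes, so a few others with large rises may weigh heavily in that value. With genes picked in 1 experiment and measured in the other the difference was -16 and -21 points. Among genes with a control signal above the median it was -16.9 points (-29.8 to -2.09). These values argue against size of the rise and low signal as the whole cause. The split by experiment cannot decide on selection. Its 383 and 377 other genes were picked by 1 untested difference, so some may hardly have risen in the other experiment. For such genes the control array shared by both parts of the share moves it away from 0. The 2 intervals resample genes on the same arrays, so they carry no spread between arrays. A faster loss of direct p53 target transcripts, or indirect activation of the other genes, may account for it, but no half-life was measured and neither was tested. Some of the other genes may also have followed the temperature, which cannot be told apart from p53 here.

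After recovery the mitosis list had a median of -0.85 against control and the replication list of -0.01, with no mitosis gene called over all genes without the block. By camera with an estimated correlation, adjusted p was 0.486 for the mitosis list and 0.837 for the histones, and with the block as well it was 0.0842 for each. Among the members of each list above its median signal, the mitosis median still lay below the replication median by a difference of -0.885 log2 units (95% bootstrap interval -1.047 to -0.631). That argues against dim probe sets, although the interval resamples genes, which are not independent replicates, and carries no spread between arrays. Over all members the difference was -0.979 in experiment 1 and -0.643 in experiment 2, so it does not rest on a single experiment. If DNA synthesis had been back at the control level, histone transcripts should have returned too, but their median was -0.959 and -1.032 in the experiments. These values were known when that test was set. The histones may cross-hybridise and have an estimated correlation of 0.714 without the block, so they should not be read as independent measurements. That correlation also holds any difference between the experiments that the histones share. A candidate explanation is that 6 h were enough for cells to resume the G1/S program but not to reach S phase and mitosis, a hypothesis not tested here, which later recovery times or the DNA content of the cells would decide.

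Genes that moved in p53 on and went back in recovery also followed the temperature, since every p53 on array was at 32 °C. The cold-inducible genes CIRBP and RBM3 differed by 1.098 and 1.057 log2 units in p53 on, so a response to temperature may be present beside that to p53. The heat shock list, with a median of -0.54 in p53 on, may belong to it too. Camera with an estimated correlation gave that list an adjusted p of 0.513. No array of cells without the transgene is among those used here, so for each gene the 2 causes cannot be told apart.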

How the results depend on the processing

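None of the 65 named calls and no called list changed direction under the alternatives run for it, and the stem and Wnt list, not called with all arrays, went from a median of 0.06 to -0.19 and past the threshold without p53 on array 2, while the direction of its test stayed down. The replicate block moved the counts to 726 higher and 881 lower in p53 on, 539 and 476 in recovery against p53 on, and 29 and 55 in recovery against control, the overlaps to 357 and 378 and the share left of the fall to 29.7%. Among the list tests and named genes, it turned 3 list tests and 22 named values into calls and changed no other call. The mean of probe sets turned 2 further list tests into calls, and no dim filter, the stricter filter and quantile normalization 1 each. Without the dim filter the counts were 83 and 30 in p53 on, 11 genes rose in recovery, 7 had fallen and then rose, and the share left of the fall was 12.8%. With the lowest 50% left out the share left of the rise was 19.7%. The mean of probe sets gave 264 and 214, then 80 and 102, and overlaps of 97 and 68. Single probe sets gave 71 and 2, then 0 and 0, and 0 genes higher after recovery. With only the 2 groups compared the counts were 46 and 4, then 0 and 0, with overlaps of 0 and 0 and shares of 15.4% and 40.7%, where fewer arrays estimate the spread. The share of the rise was 19.7% with levels raised to the dim filter, chosen after seeing the data, 15.2% on a linear scale and 19.7% for genes picked in experiment 2, and the share of the fall was 34.5% for genes picked in experiment 1. Apart from the arrays left out and the fewer genes called, the cause was not tested.

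Quantile normalization, median centring and a variance trend kept every count within 1.5 times. Leaving out each array in turn, where the lone array is assumed to vary like the other groups, gave 3 to 46 higher and 0 to 5 lower in p53 on, 0 to 0 higher and 0 to 4 lower in recovery against p53 on, 1 to 3 higher and 0 to 0 lower against control, overlaps of 0 to 4 and 0 to 0, and shares of 15.7% to 69.3% for the rise and 24.5% to 44.9% for the fall. Limma had 2164, 1720 and 746 genes at an unadjusted p under 0.05 with all arrays, and 3742, 3114 and 1821 with the block. Leaving out 1 array ended 5 list calls and added 17. Mitosis genes in recovery against p53 on ranged from -0.274 to -0.045 in these fits, which carried no block. Leaving out an array of either group compared left the experiments unbalanced. Of 65 named calls, 4 to 25 held without 1 array, 22 with only the 2 groups, 51 without the dim filter, 60 with the mean of probe sets, 63 with either scaling and 65 with the block.

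An estimated correlation left the list medians as they were and ended the calls of all lists tested except arrest and growth targets, where in p53 on it left adjusted p = 0.0475 and in recovery 0.0384. In p53 on the others were histones (0.628), heat shock (0.513), replication -0.761 (0.257), mitosis -0.642 (0.289), apoptosis 1.353 (0.185), repair 1.562 (0.257) and feedback 1.216 (0.257). In recovery against p53 on they were heat shock (0.966), replication 0.723 (0.208), mitosis -0.139 (0.966), apoptosis -1.034 (0.155), repair -1.454 (0.208) and feedback -1.235 (0.208), and against control mitosis -0.854 (0.486), histones and the unfolded protein and integrated stress genes (0.837 each). With the block and an estimated correlation, chosen after seeing the data, no list passed. In p53 on, arrest targets at 1.625, apoptosis, mitosis and histones had adjusted p = 0.0931, replication and feedback 0.204 and repair 0.348. In recovery, arrest targets at -1.492 and apoptosis had 0.136, replication and feedback 0.326, mitosis 0.369 and repair 0.389. Against control, mitosis and histones had 0.0842 each. Replication against mitosis, at 0.862 and 0.846, had 0.0693 each. The difference in share left between listed targets and other genes ranged from -71.7 to -14.9 over its alternatives. A larger correlation between genes lowers the effective number of genes by construction. No pseudocount was varied, because the values are log2, and signal near background limits the genes left out as dim.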

Other observations

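The genes that the replicate block alone called after recovery were chosen after their values were seen, and differed from control whether or not they had moved in p53 on. Lower than control were the spindle gene CENPE (-1.66), the microcephaly gene ASPM (-1.56), DLGAP5 (-1.55), the proliferation marker MKI67 (-1.49) and the water channel gene AQP3 (-1.46), with histone HIST1H2BE at -2.00. Higher than control were the lysosomal membrane gene LAPTM5 (2.57), ABCA12 (2.31), the serpin gene SERPINB7 (2.16), the lipocalin genes LCN15 (1.91) and LCN2 (1.28), the scaffold gene AHNAK2 (1.72) and the keratin gene KRT19 (1.09). The cytochrome P450 gene CYP1B1 stood at log2 means of 5.74 in control, 6.14 in p53 on and 7.34 after recovery, so most of its difference of 1.60 arose during recovery. DLGAP5 stood at 7.71, 6.92 and 6.16. Of the 55 genes lower with the block, 38 lay further from control after recovery than in p53 on, and the others, such as HMMR (6.45, 4.71 and 4.95), lay nearer, while of the 29 higher genes 12 lay further. Picking genes by their distance from control after recovery by itself favours levels further out there than in p53 on. The counts are thus partly set by the choice and were not tested. The control levels of ABCA12 and LCN15 were under the dim filter, so the sizes of their differences are uncertain.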
